A study of Mus musculus with 5 samples.

How the data were processed

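Total RNA from GL261 cells was extracted with the RNeasy Mini plus kit and made into libraries with the TruSeq Stranded Total RNA LT kit (Gold version), per the labels' protocols. The submitters' processing notes name bcl2fastq, fastp, HISAT2 and StringTie and the build mm10, without versions. Per the file headers, each deposited file was written by StringTie 2.1.1, which estimated the coverage, FPKM and TPM of the transcripts of one merged annotation in each library, with no strand option set. The authors' deposited attributes are therefore TPM, FPKM and coverage per transcript, and no read counts. TPM values sum to 1000000 per library over all transcripts, small RNAs included, so a library in which small RNAs take a larger share has lower TPM for all other genes. Without a strand option, reads of unspliced antisense or overlapping genes cannot be told apart, and reads of near-identical copies can move between them.

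Each file lists 157895 transcripts, of which 142480 are Ensembl transcripts and 15415 were assembled from the reads. Ensembl transcripts were joined to genes through GENCODE M21 (GRCm38, the assembly that mm10 names), where 99.81% of those found had the same start. The design fixed before the data were examined sums the transcripts of each reference gene and leaves out transcripts without a reference gene. It did not foresee assembled transcripts inside reference genes, which hold 5.83% to 6.54% of TPM and exchange coverage with the reference transcripts. After the files were seen, and before any test was run, 12224 assembled transcripts were counted in the reference gene of their locus that they overlap most on the same strand; 1546 of these overlap more than 1 reference gene. Sums over reference transcripts moved with this exchange inside one group: those of Vim were 5280, 1652 and 2343 TPM in the chloride libraries, where all its transcripts summed to 6897, 7073 and 5472 TPM. The list of alternatives fixed beforehand had described the gene values as sums over reference transcripts, so counting assembled transcripts departs from that wording. The choice was looked at again, and kept, after both sets of counts were known. Sums over reference transcripts only are given as an alternative and called 5 genes higher and 6 lower, against 182 and 70. The 3192 transcripts left without a reference gene (1 of them from Ensembl) stay out of the gene tests. Gene TPM is the sum over the gene's transcripts, and fold changes on the log2(TPM + 1) scale understate the change of low genes.

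The groups follow the treatment in the labels, with 3 sodium chloride and 2 sodium propionate libraries. Genes with a mean TPM of at least 1 over the 5 libraries (13879 genes) were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), two-sided, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. No 2 libraries held identical values, and the SD of log2 differences between libraries of one group was 0.321 to 0.339. Simulated data used the chloride means of the real genes, their spreads as shrunk by the model, and normal errors independent between genes. In these data, 27.5% of changes of 0.5 on the log2 scale, 91.6% of changes of 1 and 99.1% of changes of 2 were called in this comparison of 13879 genes, and 7.98% of the calls were false. Genes that vary together were not simulated, so these shares may not hold for the real data. In a single-gene exact permutation test 3 against 2 libraries cannot give a p under 0.1, so only the model across genes was used.

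Before the data were examined, 36 gene lists were fixed. They cover propionate catabolism, short-chain fatty acid receptors and transporters, genes often raised by histone deacetylase inhibitors, the deacetylases, histones, metabolism, stress responses, immune genes, the cell cycle, cell death, matrix, glial genes, ribosomal and small RNAs and markers of other cell types. Lists with at least 5 tested members (31) were compared with all other tested genes by limma's camera with an inter-gene correlation of 0.01, by camera with the correlation estimated and by fry, which does not compare a list with other genes. Lists with fewer members are given by their members only. Genes are named by a rule fixed in advance: those past the threshold with both propionate libraries on the same side of all 3 chloride libraries, as the 12 largest increases and 12 largest decreases, leaving out predicted-gene names; from each list up to 4 members past the threshold with the largest change or, where none passed, the 2 with the smallest p, given as values, except that the values of 3 members of the cholesterol and oligodendrocyte lists are left out; and Ffar2, Ffar3, Hcar2, Slc16a1, Pcca, Pccb, Cdkn1a, H1f0, Hdac1 and Ptprc.

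Alternatives fixed in advance were a pseudocount of 0.1 TPM, a minimum mean TPM of 5, no minimum, FPKM in place of TPM, median-of-ratios scaling, TPM over protein-coding genes, voom on aligned bases divided by 100 as estimated reads, library weights, a test per transcript, the replicate number as a block and each library left out. Where 1 propionate library is left, it is assumed to vary like the chloride libraries. Added after seeing the data were reference transcripts only, genes that are the only reference gene of their locus, and protein-coding genes only.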

Results

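The transcriptome of GL261 cells, a mouse glioma line that grows in C57BL/6 mice, was measured 24 h after addition of sodium propionate or of sodium chloride, which served as the control salt. The labels give the same dose, 1 uM, for both salts. The dose is stated as labelled, and its unit could not be checked. Propionate is a short-chain fatty acid made by gut bacteria, and the labels state the aim as finding the transcriptional changes that follow propionate treatment. The files analysed held 3 sodium chloride libraries (replicates 1, 2 and 3) and 2 sodium propionate libraries (replicates 2 and 3); propionate replicate 1 was not analysed here. Aligned sequence came to 7.63, 7.37 and 7.19 Gb in the chloride libraries and to 7.44 and 7.23 Gb in the propionate libraries. A gene at 1 TPM had a mean per-base coverage between 4.73 and 4.99. The labels do not say that the libraries came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. Levels are mean gene TPM ± SD over the 3 chloride and the 2 propionate libraries, and changes are log2 fold changes (propionate minus chloride) on the log2(TPM + 1) scale ± SE, with Benjamini-Hochberg adjusted p from limma.

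Among the genes that rose after propionate were genes of the extracellular matrix and the glial progenitor genes Pdgfra and Fabp7. Among those that fell were the replication genes Mcm5 and Mcm4 and 5 members of the replication-dependent histone list, 1 of them annotated as a pseudogene. Mcm5, Mcm4 and the 4 histone genes named below lost their call with any 1 of the 5 libraries left out. So did Gsn, Clu, Acsl3, Ier5, Mthfd1l and Chkb, which are named below. Pdgfra, Fabp7 and the matrix genes Col6a3, Spp1, Col1a1 and Loxl2 lost theirs without propionate replicate 3. Fabp7, Col1a1 and Loxl2 also lost theirs without chloride replicate 1, Fabp7 without chloride replicate 2 and Loxl2 without propionate replicate 2. As lists, the matrix, glial, S phase and histone genes had a camera adjusted p = 0.929 with an estimated correlation. Of 13879 genes tested, 182 were higher and 70 were lower when assembled isoforms were counted in their gene, and 5 were higher and 6 were lower when reference transcripts alone were summed, which is the narrower reading of the fixed design. Of the 182 and 70 genes, 173 and 59 were protein-coding. The median fold of the genes that rose was 1.81 (quartiles 1.61 and 2.09), and the median fold of the genes that fell was 1.52 (quartiles 1.47 and 1.73). In all 252 genes both propionate libraries lay on the same side of all 3 chloride libraries, as they did in 34.6% of all tested genes, where chance gives 20%. Higher genes made up 72.2% of the calls, 60.8% when TPM was rescaled over protein-coding genes, 53.3% without propionate replicate 3 and 45.5% with reference transcripts only. Over all tested genes 1100 were higher and 1235 lower at an unadjusted p under 0.05, and 2060 were higher and 2738 lower among genes whose groups did not overlap. The balance at that unadjusted p depended on the scaling and on single libraries. It was 1625 higher and 1374 lower with median-of-ratios scaling, 1803 and 1552 with voom and 1600 and 1587 with TPM over protein-coding genes. It leaned lower with FPKM (1248 and 1428), with a minimum of 5 TPM (718 and 1028) and without chloride replicate 3 (847 and 1124). The median log2 change over all tested genes was 0.03 without propionate replicate 2 and -0.08 without propionate replicate 3. The counts of called genes moved with the processing and with single libraries. They were 2 higher and 1 lower with no filter on low values, 7 and 6 per transcript, 370 and 157 with median-of-ratios scaling, 629 and 405 over protein-coding genes and 708 and 358 with voom on aligned bases. They were 8 and 7 without propionate replicate 3, 114 and 24 without propionate replicate 2, 66 and 12 without chloride replicate 1, 111 and 29 without chloride replicate 2 and 127 and 47 without chloride replicate 3. The sign of the change in each of the 252 genes was the same with each of the 5 libraries left out. This had to be so, because the groups did not overlap in any of these genes, and it adds no support.

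Among the largest increases was Wfdc1 (ENSMUSG00000023336, chromosome 8, 119666365 to 119688222, plus strand, mm10), which encodes a secreted protein with a protease-inhibitor domain. It stood at 7.93 ± 0.253 TPM in chloride and 25.6 ± 1.56 TPM in propionate libraries, a change of 1.57 ± 0.10 (adjusted p = 0.00100). Egfl7 (chromosome 2, 26580014 to 26593120), a secreted factor best known from endothelium, rose from 7.32 ± 0.403 to 23 ± 2.1 TPM (adjusted p = 0.00109). Col6a3 (chromosome 1, 90765923 to 90843971), a chain of collagen VI, rose from 3.79 ± 0.103 to 12.2 ± 0.751 TPM (adjusted p = 0.00163). A pair of glutathione transferases rose as well, Gsta4 from 0.965 ± 0.388 to 7.39 ± 1.92 TPM and Gstt1 from 5.13 ± 0.411 to 18.2 ± 4.26 TPM. H2-Ab1, a chain of MHC class II, went from 1.76 ± 0.271 to 7.17 ± 1.49 TPM, and Arhgdib, a gene active mostly in blood cells, from 1.22 ± 0.0693 to 4.83 ± 0.849 TPM. Apoc1, an apolipoprotein gene, rose from 4.57 ± 1.21 to 16.8 ± 5.06 TPM, and Hhla1 from 1.39 ± 0.0685 to 5.24 ± 0.178 TPM. With reference transcripts only, Apoc1 changed by 0.21 and did not pass (adjusted p = 0.949). Egfl7, Col6a3, Gsta4, Gstt1, H2-Ab1 and Arhgdib did not pass with that setting either, while Wfdc1 did. Of the 182 higher calls, 4 were kept there.

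The largest increases also held 3 genes that share sequence with an abundant relative, so their values are uncertain. Ftl1-ps1, a copy of the ferritin light chain gene (chromosome 13, 74399694 to 74407346), was listed at 0 in each chloride library and at 39.1 and 54.3 TPM in the propionate libraries. Mir692-3 lies inside it (74407065 to 74407173) and was the largest decrease, listed at 10.6, 11.8 and 11.1 TPM in the chloride libraries and at 0.00554 and 0.000710 TPM in the propionate libraries. The value of Mir692-3 is uncertain as well, since coverage can move between it and Ftl1-ps1. Rps12l1, a processed pseudogene of a ribosomal protein, was listed at 0 in each chloride library and at 21.7 and 8.92 TPM in the propionate libraries. Rpsa-ps12, another ribosomal protein pseudogene, stood at 3.76 ± 0.583 and 11.3 ± 2.16 TPM, and with reference transcripts only its change was -0.42.

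Among the largest decreases, Cited1 (ENSMUSG00000051159, chromosome X, 102247381 to 102252181, minus strand), a transcriptional co-activator, fell from 13.3 ± 0.308 to 4.09 ± 0.169 TPM, a change of -1.49 ± 0.11 (adjusted p = 0.00109). Ptgds (chromosome 2, 25466709 to 25470046), a prostaglandin D synthase, fell from 24.5 ± 2.61 to 7.98 ± 1.68 TPM (adjusted p = 0.00423). Rab11b, a GTPase of recycling endosomes, was listed at 11.3 ± 1.24 and 3.71 ± 0.403 TPM, but its change was -0.45 on aligned bases, where it did not pass (adjusted p = 0.0531). The small nucleolar RNA Snord53 fell from 8.24 ± 0.276 to 3.20 ± 0.607 TPM. Further decreases were Tgfbi, a matrix protein induced by TGF-beta (12.8 ± 1.73 to 6.49 ± 0.697 TPM), Osmr, the oncostatin M receptor subunit (17.1 ± 1.23 to 9.02 ± 1.10 TPM), and the orphan receptor gene Mrgprf (8.11 ± 0.274 to 4.06 ± 0.00738 TPM). Rab7b, a GTPase of late endosomes, fell from 9.29 ± 0.713 to 4.75 ± 0.624 TPM, and Phf19, an accessory subunit of Polycomb complexes, from 8.07 ± 0.604 to 4.24 ± 0.0995 TPM. Chkb, a choline kinase whose locus overlaps a read-through gene, fell from 25.8 ± 3.12 to 14.2 ± 2.72 TPM. With reference transcripts only, Cited1 passed, while Ptgds, Rab11b, Snord53, Tgfbi, Osmr, Mrgprf, Rab7b, Phf19 and Chkb did not. Of the 70 lower calls, 2 were kept there. Tgfbi, Osmr, Mrgprf, Rab7b and Phf19 also lost their call without chloride replicate 1 and with either propionate library left out. Phf19 lost it without chloride replicate 2 as well, and Rab11b and Snord53 lost theirs without propionate replicate 3.

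**Figure D1:**
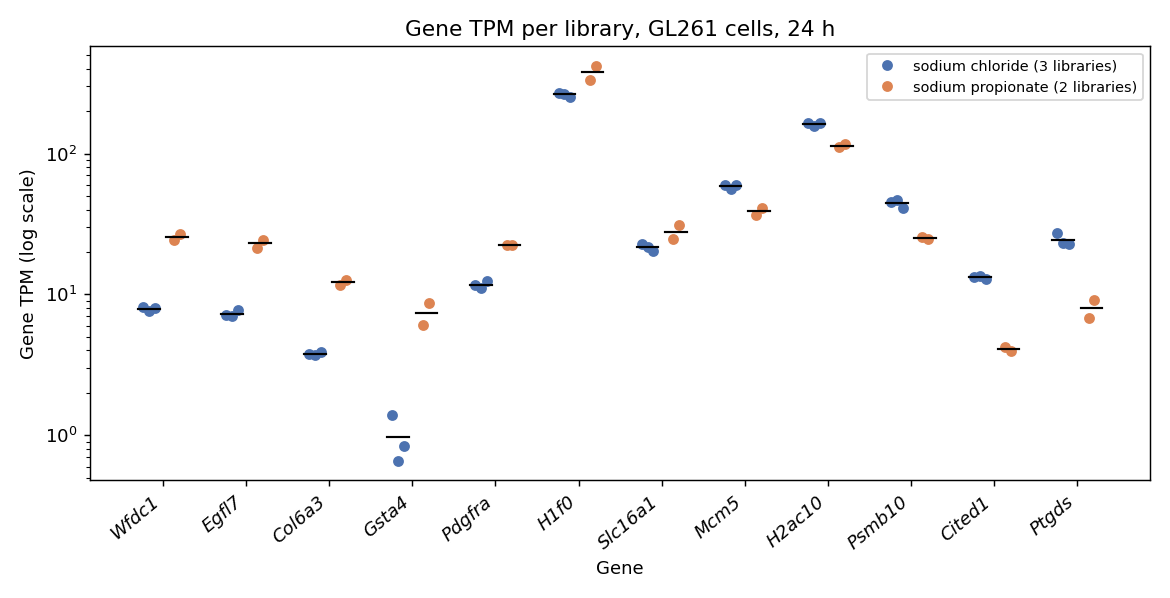
Gene TPM (log scale) in each library for 12 named genes, with points for the 3 sodium chloride and 2 sodium propionate libraries and a black bar at each group mean. Cited1 lies near 13.3 TPM in the chloride libraries and near 4.09 TPM in the propionate libraries, and Wfdc1 near 7.93 and 25.6 TPM.

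Of the 31 gene lists with at least 5 tested members, 7 were higher and 5 were lower after propionate by limma's camera with a preset inter-gene correlation of 0.01. None of the 12 calls held with an estimated correlation, where no list had an unadjusted p under 0.05, and none by fry, where 3 lists had one. In 5 of the 12 called lists (matrix, glial, deacetylase inhibitor, S phase and histone genes) the median of both propionate libraries lay beyond those of all 3 chloride libraries, and in the other 7 the libraries of the groups overlapped. Single libraries also decided lists that were not called. Without propionate replicate 3 the heat shock list and the G2 and M phase list were lower. Without propionate replicate 2 nuclear genes of oxidative phosphorylation were higher and mitochondrially encoded messenger RNAs were lower. With no filter on low values the ribosomal protein and fatty acid oxidation lists lost their call. With that setting the lists of fatty acid synthesis (adjusted p = 0.0408), G2 and M phase (lower, adjusted p = 0.0133), neuronal markers (adjusted p = 0.0124) and endothelial and pericyte markers (adjusted p = 0.0180) gained one.

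Extracellular matrix and mesenchymal genes were higher as a group, with 26 of 30 tested members above 0 and a median change of 0.26 (camera adjusted p = 2.23e-08; adjusted p = 0.929 with an estimated correlation). In this list 8 genes rose and 1 fell, and adjusted over the list alone 12 rose and 2 fell. Spp1, which encodes osteopontin, rose from 7.37 ± 1.17 to 17.7 ± 3.24 TPM, Col1a1 from 3.06 ± 0.467 to 7.77 ± 1.94 TPM and the collagen crosslinking enzyme Loxl2 from 3.10 ± 0.367 to 6.73 ± 0.668 TPM. The gene that fell was Tgfbi. Glial and neural progenitor genes were also higher (18 of 23 above 0, median 0.21, camera adjusted p = 0.00461; adjusted p = 0.929 with an estimated correlation). The growth factor receptor gene Pdgfra rose from 11.7 ± 0.628 to 22.5 ± 0.128 TPM and the lipid-binding protein gene Fabp7, typical of radial glia, from 13.5 ± 0.817 to 23.7 ± 3.14 TPM. Adjusted over the list alone 2 of these genes rose and 2 fell. Immediate early genes were higher as a list (20 of 32 above 0, median 0.10, camera adjusted p = 0.0101; adjusted p = 0.929 with an estimated correlation). Etv5, a transcription factor downstream of receptor tyrosine kinases, rose from 5.98 ± 0.801 to 13.7 ± 1.44 TPM, the ERK phosphatase gene Dusp6 from 27.9 ± 0.730 to 42.9 ± 3.61 TPM and Ier5 from 5.05 ± 0.414 to 8.59 ± 1.09 TPM. Adjusted over the list alone, 8 immediate early genes rose and 2 fell. Without propionate replicate 3, the glial and the immediate early lists were no longer called, and the matrix list was. Against the chloride mean, the medians in propionate replicates 2 and 3 were 0.11 and 0.25 for the glial list and 0.00 and 0.25 for the immediate early list.

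Propionate is known to inhibit histone deacetylases, and the genes often raised by such inhibitors were higher as a list (19 of 28 above 0, median 0.22, camera adjusted p = 0.000462; adjusted p = 0.929 with an estimated correlation). The actin-severing protein gene Gsn rose from 224 ± 24.5 to 335 ± 23.5 TPM and the secreted chaperone gene Clu from 93.5 ± 5.86 to 137 ± 13.9 TPM. Both lost their call with any 1 of the 5 libraries left out and with reference transcripts only. Adjusted over the list alone, 7 of the genes rose and 3 fell. The list median against the chloride mean was 0.12 in propionate replicate 2 and 0.31 in propionate replicate 3. The labelled dose is low for deacetylase inhibition, which is usually studied at far higher concentrations of propionate. The linker histone gene H1f0 (chromosome 15, 79028450 to 79030504), which deacetylase inhibitors raise in many cell types, stood at 263 ± 9.36 and 377 ± 58.9 TPM, a change of 0.51 ± 0.11 that did not pass over all genes (adjusted p = 0.0586). It passed in 8 alternative settings, among them median-of-ratios scaling and voom, and its adjusted p ranged from 0.00491 to 0.457 over all settings. Cdkn1a, another gene that such inhibitors often raise, was at 12.2 ± 2.34 and 12.2 ± 0.478 TPM (adjusted p = 0.982). The histone deacetylases and sirtuins were not called as a list (camera adjusted p = 0.241), with no member past the threshold. Hdac1 was at 53.5 ± 5.03 and 64.3 ± 1.34 TPM (adjusted p = 0.247) and Hdac4 at 8.46 ± 0.547 and 6.68 ± 0.765 TPM (adjusted p = 0.256).

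The receptors for short-chain fatty acids, Ffar2 and Ffar3, and the related receptor Hcar2 were listed at 0 in all 5 libraries. Of the list of such receptors and transporters 6 members were tested and none passed (camera adjusted p = 0.241). The monocarboxylate transporter gene Slc16a1 was at 21.6 ± 1.16 and 28.0 ± 4.43 TPM (adjusted p = 0.193) and its chaperone Bsg at 558 ± 16.0 and 685 ± 83.4 TPM (adjusted p = 0.171). Over 19 settings for each gene, Slc16a1 passed in 2 and Bsg in 3. Genes of propionate and branched-chain acyl-CoA catabolism showed no shift, with 12 of 25 above 0, a median of -0.00 and none past the threshold (camera adjusted p = 0.979); camera's sign was upward while the list's median and mean lay just below 0, and the median was 0.02 with median-of-ratios scaling. The subunits of propionyl-CoA carboxylase were at 5.67 ± 0.266 and 5.72 ± 0.120 TPM for Pcca (adjusted p = 0.977) and at 10.3 ± 0.838 and 8.48 ± 1.60 TPM for Pccb (adjusted p = 0.380). Mcee, the next enzyme of the pathway, was at 19.3 ± 0.407 and 24.2 ± 0.654 TPM (adjusted p = 0.146), and Suclg2, a subunit of succinyl-CoA ligase, at 25 ± 3.29 and 19.5 ± 2.57 TPM (adjusted p = 0.254).

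Replication-dependent histone genes were lower, with 58 of 62 tested members below 0 and a median change of -0.29 (camera adjusted p = 1.20e-17; adjusted p = 0.929 with an estimated correlation). Over all genes 5 of them fell, and adjusted over the list alone 35 fell and none rose. H2ac10 fell from 163 ± 5.78 to 114 ± 4.93 TPM, H2ac12 from 142 ± 6.24 to 104 ± 3.84 TPM, H2bc9 from 108 ± 7.31 to 76.4 ± 3.17 TPM and H2ac14 from 131 ± 8.86 to 87.6 ± 1.40 TPM. H2ac14 is annotated as an unprocessed pseudogene, and these near-identical genes can share reads. S phase genes were lower to a similar degree, with 38 of 40 below 0 and a median of -0.30 (camera adjusted p = 3.19e-10; adjusted p = 0.929 with an estimated correlation). The replicative helicase genes Mcm5 and Mcm4 fell, from 58.9 ± 2.15 to 39.0 ± 3.41 TPM and from 47.5 ± 2.71 to 33.1 ± 1.66 TPM. Adjusted over the list alone, 19 S phase genes fell and none rose. The G2 and M phase list was not called (29 of 40 below 0, median -0.08, camera adjusted p = 0.117), with Hjurp at 73.9 ± 5.06 and 56.4 ± 0.734 TPM and Cdc20 at 164 ± 1.19 and 125 ± 19.1 TPM (adjusted p = 0.0899 and 0.103). The small nucleolar, spliceosomal, 7SK and 7SL RNAs were lower (57 of 75 below 0, median -0.20, camera adjusted p = 0.000462; adjusted p = 0.929 with an estimated correlation), with Snord53 and Snora17 past the threshold and 12 falling adjusted over the list alone. Snora17 fell from 40.6 ± 4.19 to 26.0 ± 0.398 TPM. Without propionate replicate 3 the call of the small RNA list was lost, and its medians against the chloride mean were -0.12 and -0.38 in propionate replicates 2 and 3. Small RNA genes took 42.5%, 44.4% and 45.1% of TPM in the chloride libraries, 46.3% in propionate replicate 2 and 40.8% in propionate replicate 3.

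**Figure D2:**
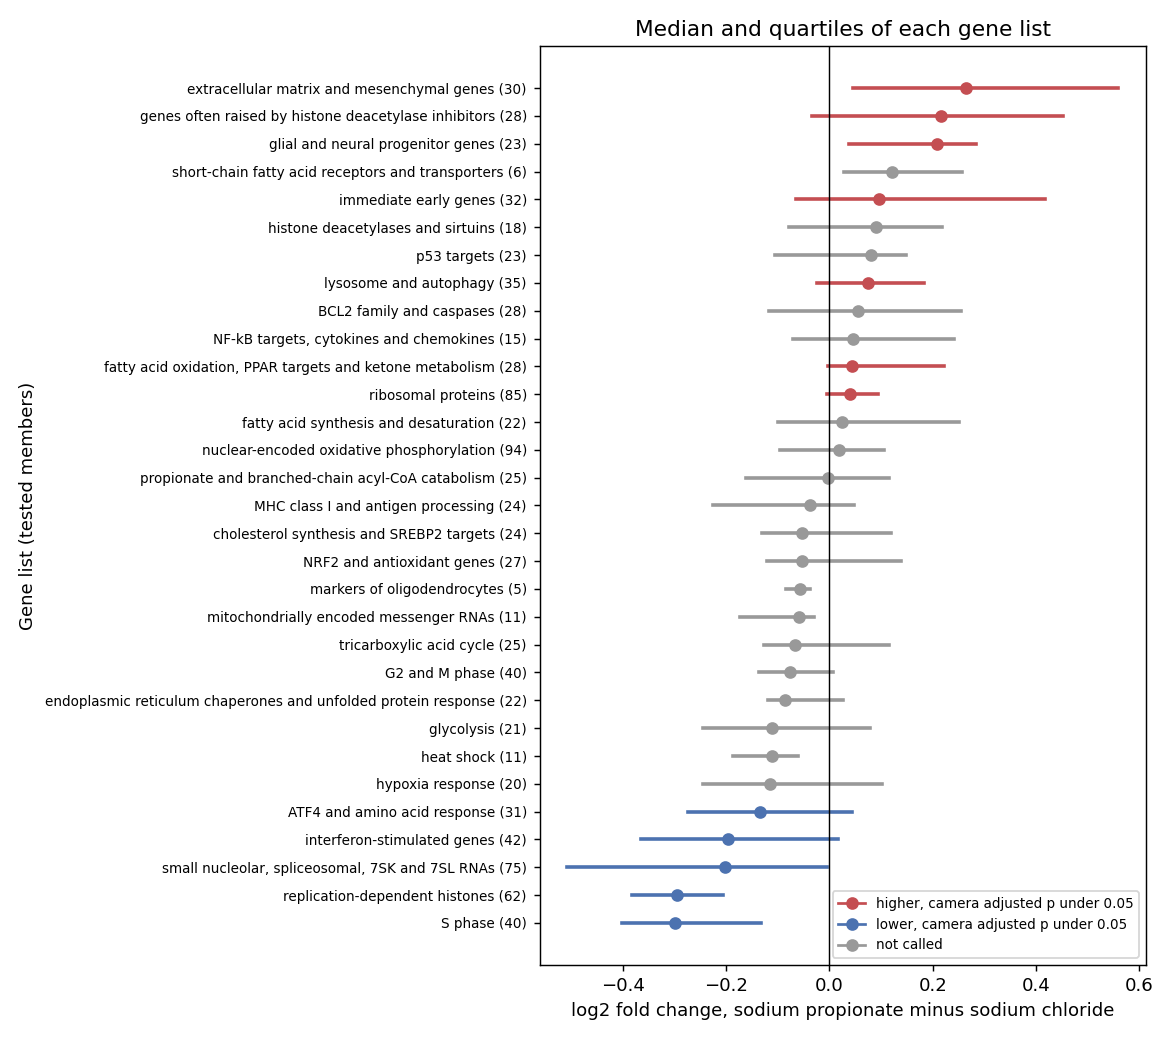
Median (point) and quartiles (line) of the log2 fold change, propionate minus chloride, over the tested members of 31 gene lists, with the number of members in parentheses; colour shows the camera call with the preset correlation. S phase genes and replication-dependent histones lie lowest, at medians of -0.30 and -0.29, and the extracellular matrix list lies highest, at 0.26.

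Interferon-stimulated genes were lower as a list (30 of 42 below 0, median -0.20, camera adjusted p = 0.000368; adjusted p = 0.929 with an estimated correlation). The median against the chloride mean was -0.18 in chloride replicate 3 and -0.14 in propionate replicate 3, so the groups overlapped. The nucleic acid sensor gene Zbp1 fell from 19.6 ± 1.99 to 11.9 ± 1.07 TPM, and adjusted over the list alone 6 genes fell. In the MHC class I and antigen processing list, which was not called (camera adjusted p = 0.241), the immunoproteasome subunit gene Psmb10 fell from 44.4 ± 3.12 to 25.2 ± 0.673 TPM. The list of NF-kB targets, cytokines and chemokines was not called either (camera adjusted p = 0.139), while 2 of its 15 members rose, the adhesion molecule gene Icam1 from 7.17 ± 0.559 to 14 ± 1.84 TPM and Tnfaip2 from 4.27 ± 0.229 to 8.21 ± 0.475 TPM; the sign of Tnfaip2 was the opposite with reference transcripts only. Genes of the ATF4 and amino acid response were lower (22 of 31 below 0, median -0.13, camera adjusted p = 0.0205; adjusted p = 0.929 with an estimated correlation). Mthfd1l, a mitochondrial folate enzyme, fell from 91.4 ± 1.80 to 67.1 ± 3.39 TPM, and 3 genes fell adjusted over the list alone. The ATF4 list was not called without chloride replicate 2 or without propionate replicate 2, and its medians were -0.24 and -0.03 in propionate replicates 2 and 3.

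Lists of energy and lipid metabolism moved little. Genes of fatty acid oxidation, PPAR targets and ketone metabolism were higher (20 of 28 above 0, median 0.04, camera adjusted p = 0.0411; adjusted p = 0.929 with an estimated correlation), with the fatty acid carrier gene Fabp3 rising from 22.2 ± 0.254 to 37.4 ± 3.21 TPM. The call was lost without chloride replicate 2, without chloride replicate 3 and without propionate replicate 3, with no filter on low values (adjusted p = 0.0793), for genes alone in their locus (0.0861) and for protein-coding genes only (0.0715). Its medians were 0.00 and 0.14 in propionate replicates 2 and 3. Fatty acid synthesis and desaturation was not called (camera adjusted p = 0.139; 0.0395 with voom on aligned bases), although the acyl-CoA synthetase gene Acsl3 rose from 48.8 ± 3.17 to 74.4 ± 7.46 TPM. Cholesterol synthesis was not called (median -0.05, camera adjusted p = 0.904), with no member past the threshold. No member of the glycolysis list passed (median -0.11, camera adjusted p = 0.295). Aldoa was at 785 ± 80.7 and 585 ± 28.4 TPM (adjusted p = 0.0899), and Gapdh, which has many pseudogene copies, was listed at 32.2 ± 21.2 and 12 ± 1.06 TPM (adjusted p = 0.201). None of the 25 tricarboxylic acid cycle genes passed (median -0.07, camera adjusted p = 0.979), and Idh2 was at 140 ± 3.83 and 165 ± 14.7 TPM. Nuclear genes of oxidative phosphorylation had a median of 0.02 over 94 members with none past the threshold (camera adjusted p = 0.295), with Ndufa4l2 at 6.69 ± 0.430 and 10.2 ± 1.27 TPM and Uqcrh at 319 ± 21.1 and 384 ± 5.10 TPM. The mitochondrially encoded messenger RNAs had a median of -0.06 (camera adjusted p = 0.295), with mt-Nd3 at 146 ± 8.82 and 125 ± 9.18 TPM and mt-Cytb at 64.9 ± 6.28 and 57.8 ± 5.78 TPM. The hypoxia response was not called (median -0.11, camera adjusted p = 0.295), with Vegfa at 24.7 ± 0.859 and 18.0 ± 3.21 TPM and Hk2 at 20.6 ± 1.01 and 17.0 ± 0.539 TPM; its median was -0.04 with voom on aligned bases. Apart from propionate catabolism, the list medians kept their sign under FPKM, median-of-ratios scaling, TPM over protein-coding genes and voom, where they could be computed.

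Lysosome and autophagy genes were higher by a small amount (26 of 35 above 0, median 0.08, camera adjusted p = 0.0218; adjusted p = 0.929 with an estimated correlation), with no gene past the threshold. The protease gene Ctsl was at 273 ± 39.2 and 355 ± 3.75 TPM and Gpnmb at 543 ± 32.1 and 672 ± 92.6 TPM (adjusted p = 0.161 and 0.195). Ribosomal protein genes were called higher (62 of 85 above 0, median 0.04, camera adjusted p = 0.0196; adjusted p = 0.929 with an estimated correlation), but the list holds the pseudogene Rps12l1 as its 1 gene past the threshold, and the call was lost among protein-coding genes only. The ribosomal call was kept with TPM over protein-coding genes, which leaves pseudogenes out as well (camera adjusted p = 0.0321). The medians in propionate replicates 2 and 3 were -0.02 and 0.19 for the lysosomal list and -0.01 and 0.10 for the ribosomal list. The sign of these medians against the chloride mean therefore rested on replicate 3. Both lists lost their call without propionate replicate 3, the lysosomal list also without chloride replicate 3, and the ribosomal list also without chloride replicate 1 and without chloride replicate 2. Among BCL2 family genes and caspases (camera adjusted p = 0.139) the pro-apoptotic gene Bik rose from 4.49 ± 0.902 to 9.52 ± 2.01 TPM. The p53 target list was not called (median 0.08, camera adjusted p = 0.314), with Btg2 at 9.99 ± 0.185 and 13.7 ± 1.42 TPM and Plk2 at 2.47 ± 0.137 and 3.87 ± 1.02 TPM. In the list of NRF2 and antioxidant genes Gsta4 rose, while the median was -0.05 and camera's sign and the mean were upward (camera adjusted p = 0.843). Endoplasmic reticulum chaperones (median -0.09, camera adjusted p = 0.621) and heat shock genes (median -0.11, camera adjusted p = 0.139) were not called. Pdia6 was at 207 ± 8.69 and 244 ± 30.3 TPM, Herpud1 at 47.2 ± 0.844 and 41.0 ± 2.71 TPM, Hsf1 at 13.9 ± 1.01 and 11.3 ± 0.644 TPM and Hsph1 at 25 ± 2.91 and 21 ± 1.18 TPM.

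Markers of cell types other than the tumor line were mostly near 0, although the neuronal and the endothelial and pericyte lists were called higher with no filter on low values. Ptprc, the pan-leukocyte marker, did not exceed 0.0457 TPM in any library. Of 20 macrophage and microglia markers 3 were tested, and Lyz2 (11.3 ± 0.769 and 16.9 ± 1.74 TPM) and Cd68 (6.94 ± 0.686 and 11.1 ± 1.43 TPM) passed adjusted over the list alone but not over all genes (adjusted p = 0.0588 and 0.0594). Each passed over all genes in 7 alternative settings, with adjusted p over all settings from 0.0138 to 0.540 for Lyz2 and from 0.0145 to 0.506 for Cd68. Tmem119, a microglial marker under the minimum for testing and chosen after its values were seen, was at 0.137, 0.0921 and 0.113 TPM in the chloride libraries and at 0.617 and 1.35 TPM in the propionate libraries. Of 14 neuronal markers 1 was tested, the microtubule-associated protein gene Map2, which rose from 17.6 ± 1.53 to 35.0 ± 3.38 TPM. Pdgfrb, a pericyte marker, was at 0.763 ± 0.216 and 2.1 ± 0.270 TPM and the endothelial gene Flt1 at 4.71 ± 0.771 and 4.67 ± 0.0814 TPM (adjusted p = 0.0868 and 0.995), and the lymphocyte kinase gene Lck at 3.37 ± 1.02 and 2.07 ± 0.980 TPM (adjusted p = 0.370). Of the oligodendrocyte markers 5 were tested and none passed, with Mog at 4.12 ± 0.818 and 3.80 ± 0.412 TPM (camera adjusted p = 0.680). The mitochondrial ribosomal RNAs mt-Rnr2 (2504 ± 191 and 2624 ± 233 TPM) and mt-Rnr1 (119 ± 41.6 and 120 ± 34.0 TPM) were the 2 ribosomal RNA genes tested and did not differ beyond their spread.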

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

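The settings with reference transcripts only, genes alone in their locus and protein-coding genes only were chosen after the data were seen, while the other settings were fixed before the data were examined.

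Against 182 genes higher and 70 lower, the counts stayed within 1.5 times for a pseudocount of 0.1 TPM, a minimum of 5 TPM, FPKM, library weights and the replicate block (146 to 266 and 48 to 105). They were 370 and 157 with median-of-ratios scaling, 629 and 405 with TPM over protein-coding genes, 708 and 358 with voom on aligned bases, 287 and 149 for genes alone in their locus and 375 and 191 for protein-coding genes only. They dropped to 2 and 1 with no filter on low values, 7 and 6 per transcript and 5 and 6 with reference transcripts only, settings in which the prior degrees of freedom of the model, 5.29 in the reported fit, were 1.68, 1.77 and 2.50. Leaving out 1 library gave 8 (without propionate replicate 3) to 127 (without chloride replicate 3) higher and 7 to 47 lower, with fewer samples in each fit; the cause of the other differences was not tested. All 252 genes kept their sign in every gene-level setting that tested them, except with reference transcripts only, where 168 of 172 and 67 of 70 did. With 1 library left out this follows from the groups not overlapping. The replicate block kept 162 and 35 of the calls on 1 residual degree of freedom, and the numbers are not shown to pair the libraries: deviations from the group mean correlated at -0.22 between both replicates 2 and at -0.19 between both replicates 3.

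Of 7 lists higher and 5 lower, 4 were higher for genes alone in their locus and 2 (without propionate replicate 3) to 8 (without propionate replicate 2) with 1 library left out; lower lists numbered 4 to 6 in every camera setting with the preset correlation. For genes alone in their locus the glial, lysosomal and fatty acid oxidation lists lost their call, and with the replicate block the lysosomal, ribosomal protein and ATF4 lists did. With an estimated correlation 0 were higher and 0 lower, and by fry 0 and 0. Signs reversed for Rpsa-ps12 (-0.42) and Tnfaip2 (-0.68) with reference transcripts only and for Tnfaip2 per transcript (-1.13), where the transcript with the highest level was tested; the cause was not tested. Named genes lost their call most often with no filter (51), per transcript (50), with reference transcripts only (46) and without propionate replicate 3 (46), and gained one most often with TPM over protein-coding genes (15) and voom (15). With the replicate block 9 lost their call, Mcm5, Mcm4, H2ac10, H2ac12 and H2bc9 among them, and 2 gained one. No other named gene that was called, in the reported fit or in the alternative, reversed. On simulated data with this number of libraries and the spread as shrunk by the model, 27.5% of log2 changes of 0.5 were called. Depth was not varied, and genes varied independently.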

Other observations

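The tests of low recovery of short RNAs, of single propionate libraries, of aligned bases and of the lists of ERK pathway output genes and nucleolar factors were chosen after the result was seen, while the tests on length, GC content and level were written before.

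For the decrease of S phase and histone genes, low recovery of short RNAs without a poly(A) tail would spare the S phase messenger RNAs, whose median was -0.30, but it stays open for the histone genes, since the small RNA list had a median of -0.20. The lists did not move to the same degree in each library: chloride replicate 1 had a small RNA median of -0.19 and a histone median of -0.00. Against the chloride mean, both medians were below 0 in both propionate libraries. The small RNA and histone medians were -0.12 and -0.35 in propionate replicate 2 and -0.38 and -0.24 in propionate replicate 3. The small RNA median of propionate replicate 2 was not below that of chloride replicate 1, so for small RNAs the groups overlapped. After the trend on length, GC content and level was removed, which explained 2.02% of the variance over 13856 genes, the medians were -0.27 for S phase genes and -0.28 for histones, and in the propionate library nearer 0 the S phase median was -0.26. A slower entry into S phase may underlie the pattern, but the cell cycle was not measured in the files used here, differences between cultures cannot be separated from the treatment, and no call held with an estimated correlation.

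Assembled transcripts raise the possibility that coverage moved between transcripts and not between groups of cells. Of the 252 genes called, 97.2% kept at least 0.5 of their log2 change in aligned bases, where none reversed, which argues against movement between isoforms of the same gene as the source of the calls as a whole. Of the called genes, 157 of the 182 higher and 58 of the 70 lower were the only reference gene of their locus. Movement between reference genes of the same locus cannot account for these calls. Movement between genes of different loci was not tested for the called genes as a whole. At the Ftl1-ps1 and Mir692-3 locus the aligned bases summed over the locus were 13.8 times higher after propionate, so movement inside the locus is not the whole cause. It stays open as a part of the cause, since Mir692-3 fell while Ftl1-ps1 rose. Reads shared with Ftl1 stay open as well and were not tested. With reference transcripts only, 5 and 6 genes were called.

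Several of the genes that rose are outputs of the ERK pathway, so a list of 10 such genes was drawn up after the called genes were known, 7 of them also in lists fixed earlier. All 9 tested members were above 0 with non-overlapping groups, which held upward for 2060 of all 13879 tested genes, where chance gives 10%, and 3 passed (camera p = 5.58e-09; p = 0.0780 with an estimated correlation). These p-values are not adjusted over lists, unlike the 0.929 given for the fixed lists. Unadjusted, camera with an estimated correlation gave p = 0.0717 for the histone list, 0.0829 for S phase and 0.147 for the matrix list. Ccnd1 rose from 34 ± 2.41 to 51.2 ± 4.84 TPM, and Epha2 was at 1.35 ± 0.155 and 2.63 ± 0.807 TPM. The call of Ccnd1 was lost with any 1 of the 5 libraries left out. The median with the trend on length, GC content and level removed was 0.54. A list chosen from the same data cannot decide whether ERK output was higher, for which phosphorylated ERK would have to be measured.

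A list of 95 nucleolar ribosome assembly factors was drawn up in the same way. Of these 86 were below 0, 63 of them with non-overlapping groups, which held downward for 2738 of all 13879 tested genes, where chance gives 10%, and 8 fell (camera p = 6.57e-15; p = 0.149 with an estimated correlation). Here too the p-values are not adjusted over lists. The median was -0.24 and ranged from -0.32 to -0.16 with 1 library left out. Dkc1 fell from 35.6 ± 1.61 to 25.2 ± 0.803 TPM and Heatr1 from 15.7 ± 0.830 to 10.5 ± 0.591 TPM. Both lost their call with any 1 library left out, with library weights, with the replicate block and with reference transcripts only.

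Of the 10 ways to split the 5 libraries into 3 and 2, the real one called 252 genes and the highest other 7; a share under 0.05 is not possible with 10 splits. Genes listed at 0 in every library of one side and above 0 in every library of the other numbered 4 in the real split and 6 in the highest other.

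In the chloride libraries Mbp was at 781 ± 92.8 TPM, S100b at 202 ± 6.82 TPM, Sox2 at 62.2 ± 8.69 TPM and Vim at 6481 ± 878 TPM, while 5 of the 10 oligodendrocyte markers fixed beforehand had a mean under 1 TPM. Dct, a gene of pigment cells, rose from 29.8 ± 0.883 to 56.6 ± 3.96 TPM, and Cd74, a partner of MHC class II, was at 1.54 ± 0.654 and 3.54 ± 0.374 TPM (adjusted p = 0.108); all these genes were chosen after their values were seen.

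Of 1699 assembled loci without a reference gene, limma called 0 higher and 0 lower (smallest adjusted p = 0.0686), and 97 and 96 had an unadjusted p under 0.05. The most abundant, on chromosome 8 from 123428731 to 123434529 (mm10), stood at 2318 ± 231 and 3098 ± 294 TPM (adjusted p = 0.639). A locus on chromosome 1 from 170945391 to 170946165 stood at 1798 ± 167 and 2428 ± 287 TPM (adjusted p = 0.608).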
